A study of Synechococcus elongatus PCC 7942 = FACHB-805 with 12 samples.

How the data were processed

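Total RNA of 12 samples of Synechococcus elongatus, 6 of wild type and 6 of a cikA null strain, had been hybridized to single-colour (Cy3) custom Agilent oligonucleotide arrays, 1 array per genotype at 4, 8, 12, 16, 20 and 24 h of continuous light after 2 cycles of 12 h light and 12 h dark. Each array held 15744 spots, of which 15208 were not controls: 4 probes for each of 2716 genes (2658 on the chromosome, 50 on the large and 8 on the small plasmid), probes for a bacterial luciferase reporter and other spikes, and 3752 tiling probes, 1876 per strand at a step of 24 nt, over the chromosome from 1199977 to 1245036. Per the file headers, the spot files hold intensity values in arbitrary units, made by Agilent Feature Extraction 9.5 with background subtraction and spatial and multiplicative detrending, with surrogate values for dim spots and no normalization between arrays. The deposited spot files also hold the mean spot intensity, the median local background intensity and yes/no flags, such as whether a spot is well above background. The deposited series table holds a score per gene and array for 1739 genes, made by the authors. In this table the wild-type values of each gene had a mean of 0 (largest departure 5.5e-09) and a range of 1, so each gene had been centred and scaled by its wild-type range, while the null values were not limited to that range. Whether the scaling was done on log or linear values is not stated. Across all columns the scores had a Pearson correlation, over genes that are not independent, of 0.964 with spike-in-scaled and of 0.771 with 75th-percentile-scaled log2 values treated the same way (1734 genes matched).

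For the reported values, log2 processed signal was taken minus the 75th percentile of the array over non-control probes, replicate spots were averaged per probe and the 4 probes averaged per gene. Of 130368 gene spot measurements 943 that the software marked as non-uniform or population outliers were left out. Genes with a probe well above background on at least 3 of 12 arrays were tested, 2697 in all, of which 1048 are described as hypothetical, and 19 were left out. Probes were saturated on at least 1 array in 20 genes. The number of arrays limits the precision: with 1 array per genotype and time, the spread comes from the departures of both time courses from their fitted curves.

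The 12 arrays were fitted together in limma 3.58.1 (R 4.3.3 with data.table, version 1.17.8) with a mean and a 24 h cosine and sine term per genotype, which leaves 6 residual degrees of freedom. The square root of limma's prior variance, a typical residual SD, was 0.199 and the prior degrees of freedom 2.86. The moderated F test of the curve terms was used for a rhythm in wild type, in the null and for their difference, and the moderated test of the genotype means for the mean level. Adjusted p-values are Benjamini-Hochberg values with a threshold of 0.05. Rhythmic genes with a fitted peak from 6 to before 18 h were called dusk-phase and the others dawn-phase. Differences are null minus wild type. Where a probe was not above background, a bound on the difference was computed with its signal set to no less than that of the lowest gene spot above background on the same array.

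Before the data were examined, the tests, the alternatives, the rule for named genes and 24 gene lists were fixed. Lists were matched on the array's gene descriptions, because none of the array's gene IDs was in the gene name table available (2785 genes, 0 IDs found). The lists were the core clock, clock input and output, sigma factors, glycogen synthesis, glycogen breakdown and oxidative pentose phosphate pathway, photosystem II, photosystem I, phycobilisome, carbon fixation and carboxysome, ATP synthase, NAD(P)H dehydrogenase, terminal oxidases, ribosomal proteins, aminoacyl-tRNA synthetases, tetrapyrrole synthesis, chaperones and Clp proteases, nitrogen assimilation, cell division and cell wall, DNA replication and repair, type IV pili and competence, high light and iron stress, two-component regulators, purine and pyrimidine synthesis, and RNA polymerase core. Of these, 22 had at least 3 tested genes and were tested with camera (preset correlation 0.01, or an estimated correlation as the alternative) and with a two-sided Fisher exact test for the share of rhythmic genes. Named genes were cikA and the kai genes, the 10 widest fitted swings among the dusk-phase and among the dawn-phase genes, the 10 highest and 10 lowest mean differences with 1 sign at 6 of 6 times, up to 4 members with the smallest p of each list that leads a comparison, and the 5 genes with the smallest p where none passed. The neighbours of cikA were chosen by position.

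Alternatives were normexp background correction (offset 50), quantile normalization, median scaling, the deposited scores, no filter on dim probes or a filter on all 12 arrays, the median of probes, slide as a block, a trend in the spread, each genotype fitted alone, periods of 22 h and 26 h, time as a block for mean levels, and each array left out in turn. Scaling to the spike-in probes, the 75th percentile of gene probes alone and leaving out both 4 h arrays were added after the data were seen. Arrays with the same scan date in the file headers were taken to share a slide.

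The procedure was tested on simulated data with the spread of these arrays, with the 2697 tested genes in the step. Noise was drawn independently for each gene and array, without a slide effect or genes that move together, and the rhythms were exact 24 h curves. The rates below therefore need not hold for the real arrays. Rhythms with a swing of 1 or 2 (log2) in wild type alone were recovered for 46% and 91% of genes, and their difference from the null for 10% and 61%. Mean differences of 0.5 and 1 were recovered for 55% and 86%. Of 142 rhythm calls 5 were false, of 75 difference calls 4, of 149 mean-level calls 8, and in the null 0 genes were called. The median error of the peak time was 0.46 h. A list shifted on purpose had a camera p of 2.94e-18, and 1 of 100 random lists had a p under 0.05.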

Results

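Transcript levels were measured in the cyanobacterium Synechococcus elongatus PCC 7942, in wild-type cells and in cells that lack cikA. This gene encodes a histidine kinase that passes light and metabolic input to the circadian clock and takes part in its output. Cultures of both genotypes went through 2 cycles of 12 h light and 12 h dark and were then released into continuous light. Total RNA was taken at 4, 8, 12, 16, 20 and 24 h, with 1 single-colour array per genotype and time, so 6 arrays per genotype and 12 in all. No time point has a replicate. The errors and p-values below measure only the departures of these arrays from smooth daily curves and say nothing of other cultures. The array carried 4 probes for each of 2716 genes, of which 2697 were tested. Between 91.4% and 98.7% of the gene probes of an array were well above background. The 75th percentile of signal ran from 566 in wild type at 8 h to 1413 in wild type at 20 h. By the scan date in the file headers the arrays fell into 2 groups, taken here as 2 slides, although no slide label was read. Slide 1 held wild type at 4 to 16 h and the cikA null at 4, 8 and 20 h, and slide 2 held the others. Levels are log2 signal relative to the 75th percentile of the array. Gene names are those of the array's annotation, each with its gene ID. Coordinates are the chromosome positions spanned by a gene's probes, in a genome build that the annotation does not name.

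The loss of cikA was visible on the arrays. The gene described as multi-sensor hybrid histidine kinase (637799056, probes from 638399 to 639019) had a mean level of -0.47 (SD 0.77 over 6 arrays) in wild type and -5.31 (SD 0.26 over 6 arrays) in the null. The fitted difference of -4.84 ± 0.23 (SE; limma adjusted p = 1.04e-05) was negative at 6 of 6 times, but averages probes at background and is not a measure of the size of the loss. Its identity as cikA rests on this description and this loss, because no table linked the array's gene IDs to symbols. In the null, 3 of its 4 probes were not above background on any array, and their signal was at least 36.4-fold, 12.7-fold and 27.9-fold lower than in wild type. The probe at 638962 to 639019 kept its signal, at 0.20 in wild type and -0.14 in the null, and was above background on 6 of 6 null arrays. Of the nearest measured genes, the bacterioferritin comigratory protein gene (637799054) fell by 0.70 on the log2 scale (adjusted p = 0.00326). The differences of the others were -0.39 (637799055, adjusted p = 0.0511), 0.08 (glutamate-1-semialdehyde-2,1-aminomutase, 637799057, adjusted p = 0.632) and 0.39 (637799058, adjusted p = 0.0511).

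The wild-type time course addressed which transcripts cycle in continuous light. Genes with an evening peak had the widest swings. The gene of the sigma factor SigC (637800290), which directs RNA polymerase to a subset of promoters, changed by 7.30 ± 1.36 (log2, peak to trough of the fitted curve ± SE) with a peak at 8.6 h. The 3 neighbouring genes of the pyridine nucleotide transhydrogenase, which exchanges reducing equivalents between NADH and NADPH, changed by 6.19 ± 1.11 (637800045), 5.93 ± 0.96 (637800046) and 5.69 (637800044), with peaks at 9.1, 9.3 and 9.4 h. Genes with a peak near dawn moved less. The gene of a conserved protein YCF21 (637798497) changed by 2.10 ± 0.22 with a peak at 20.3 h, and that of cellulose synthase (637798873) by 1.83 ± 0.27 with a peak at 21.2 h. In all, 253 genes (9.38%) passed the limma test for a 24 h rhythm, and 808 had an unadjusted p under 0.05. Of the 253 genes, 99 had a fitted peak between 6 and 18 h (dusk-phase genes) and 154 had a peak outside it (dawn-phase genes). Peaks were clustered, with 80 genes from 8 to 12 h and 140 from 20 to 24 h.

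Among the other dusk-phase genes with the widest fitted swings, a hypothetical protein (637799250) changed by 8.25 ± 1.74 (adjusted p = 0.0448) and elongation factor EF-G (637800527) by 4.56 ± 0.70 (adjusted p = 0.0232). A TetR-family regulator (637799010) changed by 4.53 ± 0.93 (adjusted p = 0.0408) and a possible ribosomal protein L36 (637800000) by 4.36 ± 0.92 (adjusted p = 0.0449). The hypothetical proteins 637800784 and 637798710 changed by 4.80 and 4.63. The adjusted p was 0.0319 for SigC and 0.0249 to 0.0299 for the transhydrogenase genes. Among dawn-phase genes the widest fitted swing was that of a thiol oxidoreductase-like gene (637799893), 2.71 ± 0.55 with adjusted p = 0.0400. This gene was not above background on 2 of 6 wild-type arrays, and its swing was 0.28 (adjusted p = 0.724) with normexp background correction and 1.79 with slide as a block. It was followed by 637798770 (2.31 ± 0.38), 637800238 (2.30 ± 0.42), a probable glycosyl transferase (637800472, 2.25 ± 0.36) and 637799784 (2.21 ± 0.16, adjusted p = 0.00263). A gene like the cell death suppressor Lls1 (637800609) changed by 2.10 ± 0.21, but was not above background on 1 of 6 arrays, and its swing was 0.36 (adjusted p = 0.263) with normexp. The genes 637800259 and 637798890 changed by 2.08 and 1.99. With normexp the swings of 637800259 and of the glycosyl transferase were 0.60 (adjusted p = 0.118) and 1.25. The clock genes kaiB and kaiC, which encode parts of the oscillator, did not pass. Their wild-type swings were 1.97 ± 0.57 (637799646, peak 8.2 h, adjusted p = 0.109) and 2.14 ± 0.52 (637799645, peak 8.9 h, adjusted p = 0.0644). For kaiA (637799647) the fitted swing was 0.66 ± 0.40 with adjusted p = 0.505. Of the list of clock input and output genes 0 were matched by the array's names.

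**Figure D1:**
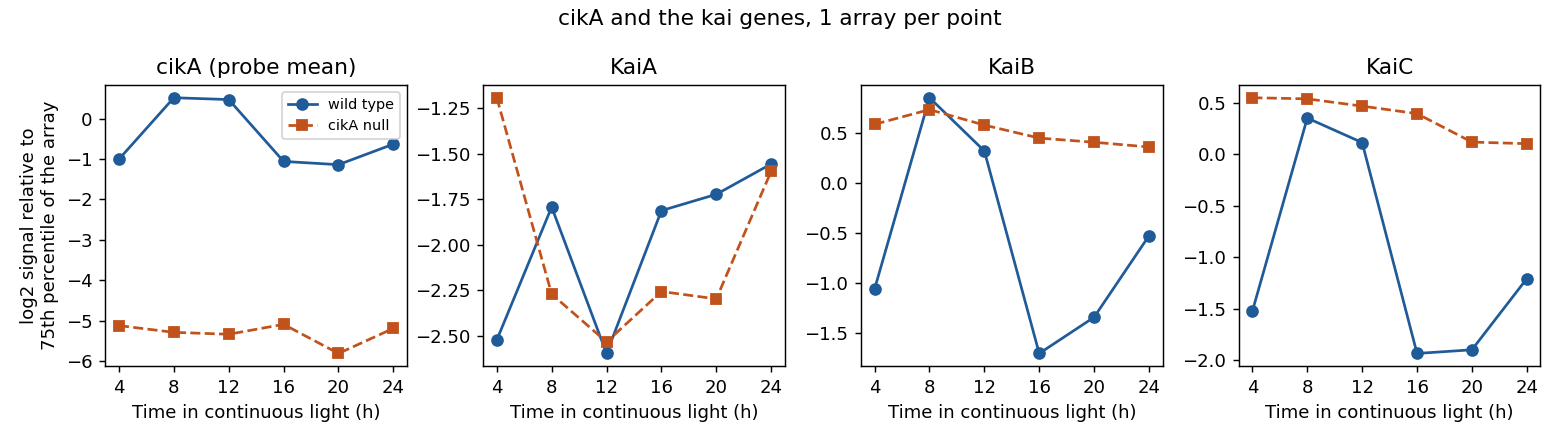
Levels of cikA (mean of 4 probes), kaiA, kaiB and kaiC (log2 signal relative to the 75th percentile of the array) against time in continuous light (h); each point is 1 array, and lines join the arrays of a genotype. In wild type kaiB and kaiC were highest at 8 h, and in the cikA null kaiC lay above wild type at 6 of 6 times.

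Genes of glycogen breakdown and the oxidative pentose phosphate pathway, which release stored carbon and NADPH, made up the list with the largest share of genes rhythmic after adjustment over all genes. Of its 9 members 5 were rhythmic in wild type (7 adjusted over the list alone), all 5 of them dusk-phase (Fisher exact adjusted p = 0.0141 over 22 lists). Glucose-6-phosphate 1-dehydrogenase (637800782) changed by 3.80 ± 0.80 and opcA (637800781), whose product activates that enzyme, by 3.71 ± 0.65. Transaldolase (637800745) changed by 3.31 ± 0.51 and 6-phosphogluconate dehydrogenase (637798444) by 3.26 ± 0.59. The list's fitted level was higher at 12 h than at 24 h by a median of 2.05 (camera adjusted p = 9.19e-07; adjusted p = 0.895 with an estimated correlation). Of the sigma factors 2 of 7 were rhythmic (6 adjusted over the list alone), SigC and the principal factor SigA (637799990, 2.07 ± 0.38, peak 7.0 h, 1.29 with spike-in scaling). Photosystem I, which reduces ferredoxin in the light reactions, had 5 rhythmic genes of 13, all 5 dusk-phase (10 adjusted over the list alone, Fisher exact adjusted p = 0.0526). Dusk-phase here need not mean a peak near 12 h. Relative to the wild-type mean, the level of all 13 genes in wild type averaged 0.44 at 4 h, 0.29 at 8 h and -0.07 at 12 h. Among the 5 rhythmic genes were psaE (637799753, 1.03 ± 0.17) and the psaA core protein (637800494, 1.02 ± 0.18, with a saturated probe on 10 arrays). Their swings were 0.66 and 0.28 with quantile normalization and 0.57 and 0.14 with spike-in scaling, and neither passed there (adjusted p = 0.0544, 0.368, 0.0595 and 0.818). Phycobilisome genes, which encode the light-harvesting antenna, had 4 of 14 (8 adjusted over the list alone), with 1 in the dusk and 3 in the dawn class. Of the tetrapyrrole synthesis genes 3 of 17 were rhythmic (6 adjusted over the list alone), the 3 subunit genes of the light-independent protochlorophyllide reductase with peaks at 9.6, 9.8 and 10.1 h.

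Members passed in smaller shares in photosystem II (2 of 24; 2 adjusted over the list alone), DNA replication and repair (3 of 39; 3), two-component regulators (3 of 42; 3) and ribosomal proteins (3 of 54; 0). The same held for nitrogen assimilation (2 of 22; 2), chaperones and Clp proteases (2 of 26; 1), cell division and cell wall (1 of 21; 1), type IV pili and competence (1 of 14; 2) and purine and pyrimidine synthesis (1 of 18; 0). By limma 0 genes passed in the core clock (3 members), high light and iron stress (7) and RNA polymerase core (6), with 2, 1 and 2 adjusted over the list alone and 2, 2 and 3 at an unadjusted p under 0.05. By limma 0 also passed, over all genes and adjusted over the list alone, in carbon fixation and carboxysome (11 members), ATP synthase (9), NAD(P)H dehydrogenase (15), terminal oxidases (3) and aminoacyl-tRNA synthetases (23). Their counts at an unadjusted p under 0.05 were 2, 0, 3, 0 and 3. Of the 2 matched glycogen synthesis genes, glucose-1-phosphate adenylyltransferase (637799014) and the branching enzyme (637799511), 0 passed and 0 had an unadjusted p under 0.05 by limma, with swings of 0.42 ± 0.23 and 0.49 ± 0.23.

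The count of 253 rested on the slide, the period, the shared spread and single arrays: with each genotype fitted alone 0 genes passed, with a 26 h period 77 and with a 22 h period 430, 7 of the 60 orderings of the wild-type arrays gave as many genes, with slide as a block 0 genes passed (596 unadjusted), since the lowest adjusted p rose to 0.0544 while the median swing of the 253 genes went from 1.24 ± 0.21 to 1.30 ± 0.27 (median SE), and without the wild-type array at 20, 8 or 12 h 0, 1 or 3 passed, without that at 4 h 939, and without a null array at 8, 12, 16, 20 or 24 h 158, 61, 10, 8 or 67. No slide holds a whole wild-type cycle, so the rhythm has no value within a slide, and scaling moved the division into 99 dusk-phase and 154 dawn-phase genes to 265 and 112 after normexp background correction, 132 and 117 after quantile normalization, 114 and 83 after median scaling, and 69 and 1770 after scaling to the spike-in probes.

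The cikA null time course addressed whether transcripts still cycle without this kinase. In the null the genes called rhythmic in wild type had flatter fitted curves. SigC had a fitted swing of 1.67 in the null and 7.30 in wild type, and the transhydrogenase gene 637800045 had swings of 2.34 and 6.19. Across the 253 rhythmic genes the median swing was 0.50 in the null and 1.24 in wild type. Over all 2697 tested genes, which were not chosen by their rhythm, the medians were 0.397 and 0.522, and the swing was wider in wild type in 1693. Among the 253 rhythmic genes the null swing was smaller in 247, and their median ratio of null to wild type was 0.374. By limma 0 of 2697 genes passed in the null (360 at an unadjusted p under 0.05; lowest adjusted p = 0.154). The 5 genes with the smallest p, which do not hold up, were a probable glycosyltransferase (637800471, swing 1.96), excinuclease subunit A (637799264, 1.16) and the hypothetical proteins 637800229 (1.97), 637800571 (1.48) and 637798498 (1.32). With the deposited values 31 genes passed in the null, with spike-in scaling 4, without the wild-type array at 4 h 4, and without both 4 h arrays 9. Choosing genes in wild type lowers the ratio by selection. In the reverse choice, the 253 genes with the smallest null p, the median ratio of wild type to null was 0.725. No gene was rhythmic in both genotypes, so a difference in peak time was not measured.

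The difference in rhythm between genotypes, tested directly, addressed whether the flattening in the null exceeds the spread. The 5 genes with the smallest p did not hold up. They were 637799784 (swing 2.21 in wild type and 0.35 in the null, adjusted p = 0.116), YCF21 (637798497; 2.10 and 0.14), 637798959 (1.69 and 0.28, with a saturated probe on 7 arrays), 637798909 (1.12 and 0.44) and 637800861 (1.81 and 0.25). By limma 0 genes passed, with 202 at an unadjusted p under 0.05 where 135 are due to chance. A rhythm called in wild type and not in the null was therefore not shown to differ for any single gene. Without the wild-type array at 4 h 119 genes passed, and without both 4 h arrays 63 did.

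By groups, the fitted change between 12 h and 24 h differed for 3 lists. The glycogen breakdown and oxidative pentose phosphate list had a median change of 2.05 in wild type and 0.99 in the null, and its change was smaller in the null (camera adjusted p = 0.0254). In the null alone its change passed as well (adjusted p = 0.00172). Photosystem I had a median change of 0.06 in wild type and -0.11 in the null (adjusted p = 0.0280). Ribosomal proteins had a median change of 0.03 in wild type and 0.33 in the null (adjusted p = 0.0170), and passed in the null alone (adjusted p = 1.26e-05). Each of these differences had adjusted p = 0.972 with an estimated correlation, and each change in the null adjusted p = 0.953 with an estimated correlation. With slide as a block the adjusted p of the difference was 0.00650, 0.230 and 0.0153 for the 3 lists. With this block 8 lists passed: glycogen breakdown, ribosomal proteins, the core clock (0.0267), sigma factors (0.0267), type IV pili and competence (0.0213), high light and iron stress (0.0213), aminoacyl-tRNA synthetases (0.0213) and purine and pyrimidine synthesis (0.0183). An estimated correlation was not combined with the block, and without the block each of these 8 lists had adjusted p = 0.972 with it. The nitrogen assimilation list passed in the null, with a median change of 1.14 (adjusted p = 0.0176; adjusted p = 0.953 with an estimated correlation; 0.0702 with slide as a block). In wild type its median was 1.07 (adjusted p = 0.0670; adjusted p = 0.963 with an estimated correlation; 0.00188 with slide as a block). With the block the list thus passed in wild type and not in the null. The difference itself had adjusted p = 0.996 (0.0812 with slide as a block). The 4 h arrays stood apart for this list. Relative to the wild-type mean, its mean level in the null was -1.76 at 4 h, 0.46 at 12 h and 0.27 at 24 h, and in wild type -1.84, 0.38 and 0.27.

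The differences rested on single arrays: for glycogen breakdown the call ended without wild type at 4, 8 or 12 h (adjusted p = 0.0928, 0.0940, 0.219) or the null at 12 or 24 h (0.0654, 0.0739), for ribosomal proteins without wild type at 4 or 8 h (0.299, 0.272), the null at 12 or 20 h (0.0654, 0.0560) or both 4 h arrays (0.557), for photosystem I without wild type at 16, 20 or 24 h (0.122, 0.0648, 0.304) or the null at 4, 8 or 12 h (0.153, 0.0979, 0.114), and for nitrogen assimilation in the null without the null at 4 or 8 h (0.273, 0.152). Without the null at 12 h 0 lists differed and without wild type at 24 h 5. Normexp background correction ended the glycogen breakdown and photosystem I calls (adjusted p = 0.199 and 0.513), and that of photosystem I also ended with quantile normalization (0.202), the deposited values (0.890), spike-in scaling (0.0906) and a 22 h period (0.111).

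**Figure D2:**
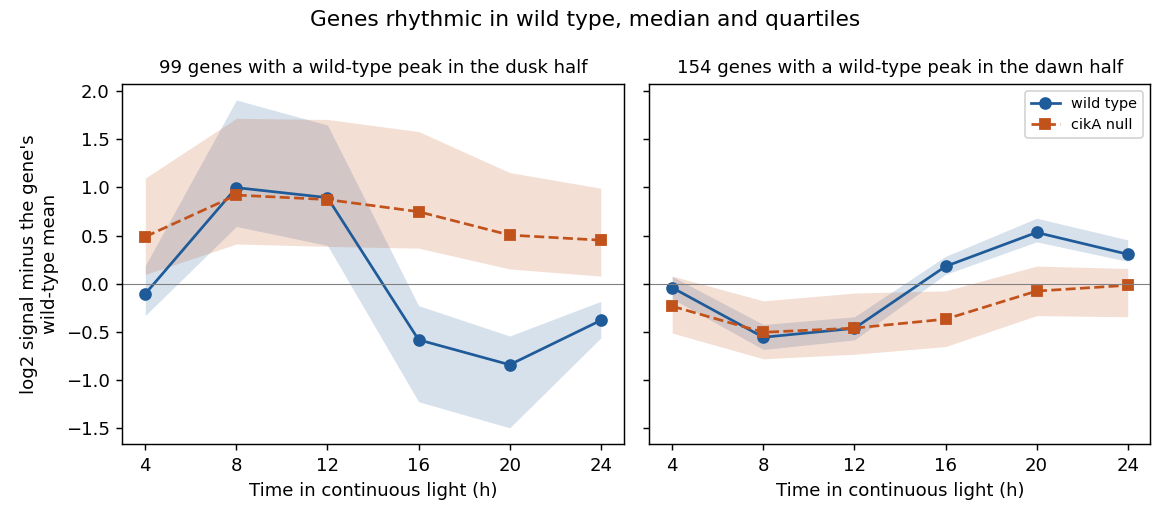
Median (line and points) and quartiles (band) of the 99 dusk-phase and 154 dawn-phase genes at each time in continuous light (h), as log2 signal minus the gene's wild-type mean, for wild type and the cikA null, 1 array per point. The dusk-phase median in the null stayed between 0.45 and 0.92, while in wild type it went from 0.89 at 12 h to -0.84 at 20 h.

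The comparison of mean levels over the cycle addressed which transcripts run higher or lower without cikA. The largest rise was that of a transcriptional regulator of the XRE family with a cupin sensor domain (637800483, probes from 2107374 to 2107915). Its mean was -5.60 in wild type and 0.57 in the null. In wild type its 4 probes were above background on 0, 4, 2 and 1 of 6 arrays, so the fitted difference of 6.17 ± 0.27 (adjusted p = 1.04e-05, higher at 6 of 6 times) is not a measure of its size. Against the lowest spot above background the level in the null was at least 42.7-fold higher (5.41 on the log2 scale). The clock gene kaiC rose by 1.38 ± 0.26 (adjusted p = 0.00620, 6 of 6 times). The mean of kaiB rose from -0.58 to 0.52 (SE of the difference 0.29, adjusted p = 0.0232, 5 of 6 times), whereas kaiA differed by -0.02 ± 0.20 (adjusted p = 0.946). A winged helix response regulator (637800864) fell by 1.68 ± 0.17 on the log2 scale. SigC rose by 2.84 ± 0.68, a call that ended with time as a block (adjusted p = 0.0549) and without the null at 24 h (0.0517), while SigD (637799084), another group 2 sigma factor, fell by 1.23 ± 0.16. In all, 329 genes were higher and 322 lower in the null by limma, 88 and 39 of them by 2-fold or more.

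**Figure D3:**
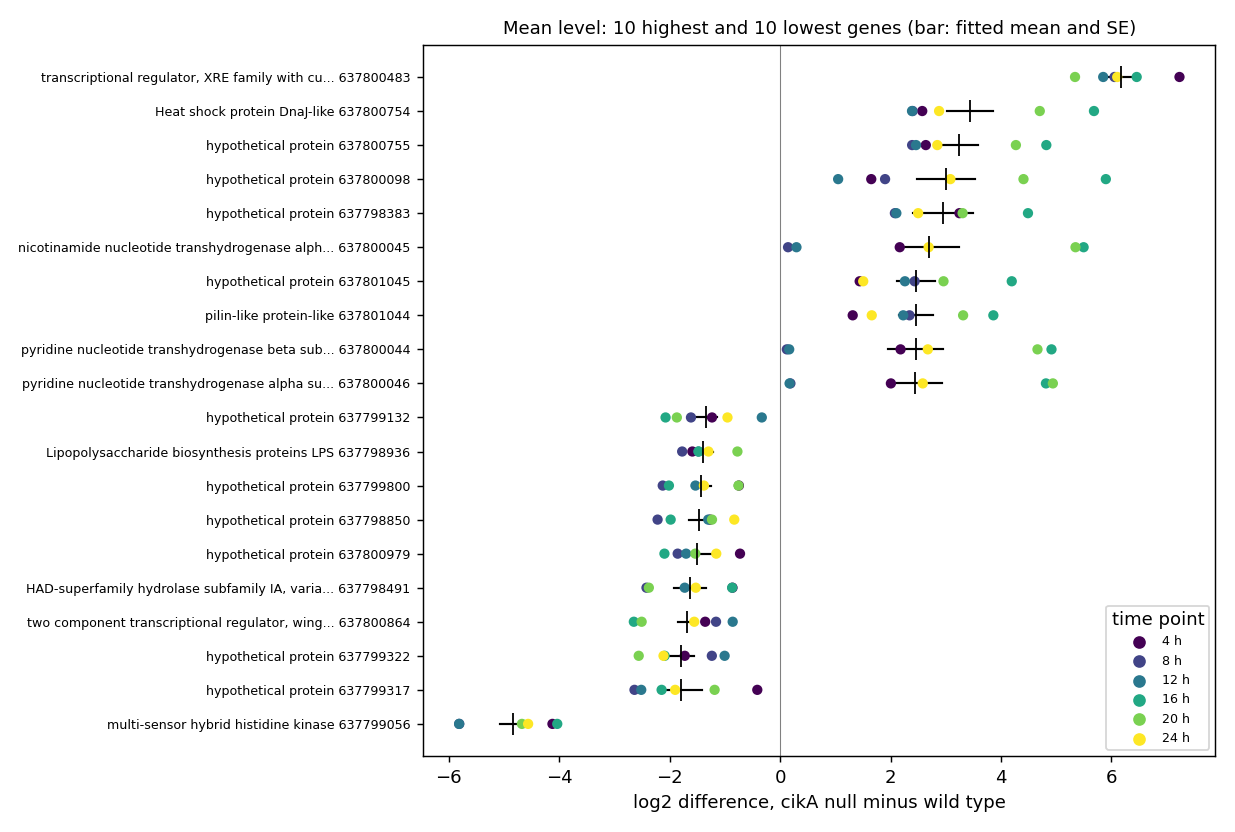
Difference in level (log2, cikA null minus wild type) of the 10 highest and 10 lowest called genes with 1 sign at 6 of 6 times; coloured points are the 6 time points (1 array per genotype each), and the vertical tick and horizontal bar are the fitted mean difference and its SE. The largest fitted values are 6.17 for the cupin-domain regulator 637800483, whose wild-type signal was mostly not above background, and -4.84 for cikA, whose signal in the null was mostly not above background.

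The highest genes with 1 sign at 6 of 6 times included neighbouring sets. A DnaJ-like heat shock protein (637800754) and the hypothetical protein next to it (637800755) rose by 3.44 ± 0.42 and 3.24 ± 0.34, and a pilin-like gene (637801044) and its neighbour (637801045) by 2.45 ± 0.31 and 2.47 ± 0.34. The 3 transhydrogenase genes rose by 2.69 ± 0.56 (637800045), 2.45 ± 0.50 (637800044) and 2.45 ± 0.48 (637800046). The hypothetical proteins 637800098 and 637798383 rose by 3.00 ± 0.52 and 2.95 ± 0.54. After cikA the lowest genes were mostly hypothetical proteins: 637799317 (-1.80 ± 0.39), 637799322 (-1.79 ± 0.22), 637800979 (-1.51 ± 0.28), 637798850 (-1.47 ± 0.18), 637799800 (-1.42 ± 0.17) and 637799132 (-1.35 ± 0.21). A hydrolase of the HAD superfamily (637798491) differed by -1.63 ± 0.29 and a lipopolysaccharide biosynthesis gene (637798936) by -1.40 ± 0.19. The adjusted p of these genes was at most 0.0108, and each kept its sign at 6 of 6 times. Of genes higher at 5 of 6 times, SigC and the hypothetical protein 637799250 (3.39 ± 0.87, adjusted p = 0.0217) lay in the same range.

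The rhythmic classes moved apart in mean level. Of the 99 dusk-phase genes 90 had a higher mean in the null, and 66 genes of the class were called higher and 1 lower. Of the 154 dawn-phase genes 119 had a lower mean, and 66 were called lower and 9 higher. The median difference was 0.74 for dusk-phase and -0.24 for dawn-phase genes, a gap of 0.98 (Fisher exact p = 1.38e-28 for the sign, over genes that are not independent). The median mean level of dusk-phase genes in the null lay at 0.882 of the way from their wild-type trough to their peak, and that of dawn-phase genes at 0.305. By time the gap was 0.80 at 4 h, -0.17 at 8 h, -0.04 at 12 h, 1.77 at 16 h, 1.99 at 20 h and 1.19 at 24 h. The classes were chosen by the phase of these same wild-type arrays. A flatter null alone would therefore lower the gap at 8 and 12 h and raise it at 16 to 24 h. The course of the gap over time is thus no separate evidence of a shift in mean level. With slide as a block the gap was 0.90, and from the pairs of arrays on the same slide (4, 8 and 24 h) it was 0.64. The nearest wild-type array to the null at 8, 12, 16 and 20 h was that at 12 h, with root mean square distances of 0.44, 0.44, 0.44 and 0.48. The null arrays at 4 h and 24 h lay nearest to wild type at the same time (0.58 and 0.54).

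Among gene lists, 3 were higher in the null by camera, each with adjusted p = 0.773 with an estimated correlation. In glycogen breakdown and the oxidative pentose phosphate pathway 5 of 9 genes rose, 0 fell and 4 were not called (5 and 0 adjusted over the list alone; adjusted p = 0.0251). The activator gene opcA rose by 1.64 ± 0.33, 6-phosphogluconate dehydrogenase by 1.37 ± 0.29 and glycogen phosphorylase (637798650) by 1.22 ± 0.27, and the mean of transaldolase went from 0.22 to 1.33 (adjusted p = 0.0147; 0.0800 with time as a block). In photosystem I 6 of 13 rose and 0 fell (6 and 0 adjusted over the list alone; adjusted p = 0.0384), and 4 rose after median or spike-in scaling. Subunit X (637798813) rose by 0.89 ± 0.17, the iron-sulfur center protein (637798943) by 0.74 ± 0.09 and subunit II (637799422) by 0.46 ± 0.08. Of the ribosomal proteins 10 of 54 rose and 0 fell (10 and 0 adjusted over the list alone; adjusted p = 0.00312). With normexp 15 rose, and with spike-in scaling 4 rose and 1 fell. In the latter the list's median went from 0.20 to 0.06, but lay 0.17 above that of all genes under both scalings. L13 (637800652) rose by 0.48 ± 0.07, S9 (637800651) by 0.46 ± 0.09 and L17 (637800654) by 0.44 ± 0.08 (adjusted p = 0.0620 with spike-in scaling). The list also holds the L11 methyltransferase (637799933), a modifying enzyme, which rose by 0.57 ± 0.11.

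With slide as a block the 3 lists had adjusted p = 0.0339, 0.0342 and 0.00217 and medians of 1.05, 0.27 and 0.21. Their medians within slide were 1.17, 0.03 and -0.11 at 4 h, -0.02, -0.09 and 0.45 at 8 h, and 1.18, 0.47 and 0.19 at 24 h. The ribosomal call ended without wild type at 8 h (adjusted p = 0.0822) and that of glycogen breakdown without the null at 8 h (0.0515). The photosystem I call ended without wild type at 8, 12, 20 or 24 h (0.0822, 0.0777, 0.0713, 0.0928), the null at 4 or 16 h (0.116, 0.0782) or both 4 h arrays (0.0623), after median scaling (0.0595), with the deposited values (0.303), with spike-in scaling (0.0710) and with a 22 h period (0.0701 in both genotypes, 0.0543 in the null alone). Without wild type at 4, 8 or 16 h 7, 1 or 6 lists passed.

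The other lists did not pass by camera, and several held called genes in both directions. Two-component regulators had 11 of 42 lower and 4 higher (12 and 4 adjusted over the list alone; adjusted p = 0.0690). Among them the chemotaxis-type kinase CheA (637799275) fell by 0.87 ± 0.07 and the CheY-like regulators 637799271 and 637799272 fell by 1.14 ± 0.11 and fell by 1.04 ± 0.10 on the log2 scale. DNA replication and repair had 10 of 39 lower and 0 higher (11 and 0 adjusted over the list alone; adjusted p = 0.0770), including a photolyase-like gene (637800308, -0.89 ± 0.17) and recN (637800220, -0.63 ± 0.13). Sigma factors had 4 of 7 higher and 1 lower (5 and 1 adjusted over the list alone; adjusted p = 0.256), including SigA (0.76 ± 0.19). The SigA call ended with time as a block (0.0951) and without wild type at 20 h (0.0522) or the null at 12 or 16 h (0.0568, 0.0624). Phycobilisome genes had 5 of 14 higher and 0 lower (6 and 1 adjusted over the list alone; adjusted p = 0.121), with the rod linker 637799472 at 0.65 ± 0.14. With spike-in scaling these counts were 2 and 2. Photosystem II had 4 of 24 lower and 0 higher (4 and 0 adjusted over the list alone; adjusted p = 0.195), with 8 lower after spike-in scaling and 6 after quantile normalization or median scaling. Among them the q(b) protein genes 637799821 and 637799310 were at -0.62 ± 0.10 and -0.60 ± 0.10, and cross-hybridization between the copies of this gene was not tested. Tetrapyrrole synthesis had 4 of 17 higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.328). Heme oxygenase (637800299) rose by 0.71 ± 0.10, and protochlorophyllide reductase subunits N (637799852) and B (637800279) rose by 1.13 ± 0.22 and 1.24 ± 0.30. The call of subunit B ended without the null at 24 h (adjusted p = 0.0517).

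The core clock had 2 of 3 higher (2 adjusted over the list alone; adjusted p = 0.216) and terminal oxidases 1 of 3 (2 adjusted over the list alone; adjusted p = 0.318). For the next 9 lists the counts adjusted over the list alone were the same except in nitrogen assimilation. Type IV pili and competence had 2 of 14 higher (adjusted p = 0.195), RNA polymerase core 2 of 6 higher (adjusted p = 0.195), and NAD(P)H dehydrogenase 2 of 15 lower (adjusted p = 0.909). Counts higher and lower were 2 and 2 of 23 aminoacyl-tRNA synthetases (adjusted p = 0.909), 3 and 3 of 26 chaperones and Clp proteases (0.909) and 1 and 2 of 22 nitrogen assimilation genes (0.909; 0 and 2 adjusted over the list alone). They were 2 and 3 of 21 cell division and cell wall genes (0.601), 1 and 1 of 7 high light and iron stress genes (0.909) and 1 and 2 of 18 purine and pyrimidine synthesis genes (0.956). By limma 0 genes were called in carbon fixation and carboxysome (11 members, adjusted p = 0.621), ATP synthase (9, adjusted p = 0.476) and glycogen synthesis (2), and 1, 0 and 0 had an unadjusted p under 0.05. The camera direction was down for nitrogen assimilation and NAD(P)H dehydrogenase, whose medians were 0.03 and 0.01. It was also down for chaperones and Clp proteases and for high light and iron stress, whose means were 0.15 and 0.08.

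With slide as a block 266 genes were higher and 267 lower, 526 of the 651 calls remained and 651 of 651 kept their sign. The blocked differences were -4.94 for cikA and 6.09 for the cupin-domain regulator (both with the same limit of background), 1.31 for kaiC and 1.02 for kaiB (adjusted p = 0.0420). In the pairs of arrays on the same slide 320 of the 329 higher and 314 of the 322 lower genes had that sign at 4 h, 270 and 295 at 8 h, and 328 and 320 at 24 h. The genes were called from means that include these pairs, so part of this agreement follows from the choice of genes. Without single null arrays at 12, 16, 20 or 24 h the higher genes numbered 205, 212, 211 or 205, without those at 12 or 16 h the lower genes 210 or 201, and the kaiB call ended without the null array at 8, 12, 16, 20 or 24 h (adjusted p = 0.0595, 0.0576, 0.0593, 0.0612, 0.0562). Scaling to the spike-in probes moved the median difference of all genes from 0.03 to -0.11 and changed the division from 329 higher and 322 lower (50.5% higher) to 210 and 459 (31.4% higher), with dusk-phase and dawn-phase medians of 0.60 and -0.38.

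At single times, with 1 array per genotype and no test, the genotypes were most alike at 12 h, when 66 genes were at least 2-fold higher and 22 at least 2-fold lower in the null. They were furthest apart at 16 h (245 higher, 93 lower) and 20 h (180 and 76), with 165 and 36 at 4 h, 56 and 61 at 8 h, and 113 and 52 at 24 h. SigC was at 4.12 in wild type and 4.14 in the null at 12 h, and at -1.94 and 4.04 at 16 h. The transhydrogenase gene 637800045 was at 1.58 and 1.87 at 12 h, and at -4.68 and 0.67 at 20 h.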

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

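The comparisons of reporter and antisense probes and the splits within a time were chosen only after the result was seen. Signal in probes that the report did not use came from the luciferase reporter genes. The array carried 5 probes for each of LuxA to LuxE, and all 60 spots of each gene were well above background. The level in the null exceeded that in wild type by 4.20 for LuxA, 4.20 for LuxB, 3.10 for LuxC, 2.18 for LuxD and 1.05 for LuxE (log2), each higher at 6 of 6 times, with limma adjusted p from 4.32e-05 to 0.000961. In wild type each of the 5 was highest at 8 h and lowest at 20 h. LuxA went from -3.00 to 1.55 in wild type and stayed between 3.08 and 3.77 in the null. The labels do not say which promoter drives each reporter gene.

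The tiling probes on the strand opposite to kaiC also gave a signal that the report did not use. Over 17 probes this antisense level was 1.29 higher in the null, at 6 of 6 times, and 89.7% of the antisense spots were above background. On the sense strand the difference was 1.30. How strand-specific the labelling was is not stated.

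For 3 gene lists the fitted change between 12 h and 24 h differed between genotypes in a test of the difference: glycogen breakdown and oxidative pentose phosphate pathway (adjusted p = 0.0254), photosystem I (adjusted p = 0.0280) and ribosomal proteins (adjusted p = 0.0170). Each had adjusted p = 0.972 with an estimated correlation. Chance could not be excluded for this count: 75 of 100 splits of the 12 arrays, drawn from 462, gave at least 3 lists, and the highest of the other splits gave 13. These splits mix times, but with arrays swapped only within a time 15 of 32 splits also gave at least 3 lists, and the highest of the others gave 7. Splits with several times the real count point to a structure of the samples or to genes of a list that move together, which no test told apart.

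For some named genes 1 array stood apart from the other 5 of its genotype, with a gap to the nearest of them, as a share of the whole range, beyond the critical value of Dixon's test. This held in 6 of 104 groups of 6 arrays, and chance gives about 1 in 20. In the null at 4 h it held for the hypothetical proteins 637799317 (0.724), 637799322 (0.753) and 637800979 (0.629), and in wild type at 4 h for 637800979 (0.725). It held in the null at 20 h for cikA (0.660) and in the null at 24 h for the winged helix response regulator 637800864 (0.693).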

How the results depend on the processing

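The spike-in scaling and the fit without both 4 h arrays were chosen only after the result was seen, as was the percentile of gene probes alone. Genes rhythmic in wild type (253) numbered 1109 with the deposited scores, 0 with slide as a block, 0 with each genotype fitted alone, 430 and 77 with periods of 22 h and 26 h, 1839 with spike-in scaling and 1171 without both 4 h arrays, and 0 to 939 with 1 array left out. In the null (0) they numbered 31 with the deposited scores, 4 with spike-in scaling and 9 without both 4 h arrays, and 0 to 4 with 1 array left out. A rhythm difference (0) was called for 1 gene with a 22 h period and 63 without both 4 h arrays, and for 0 to 119 with 1 array left out. Genes higher in the null (329) numbered 203 with the deposited scores, 210 with spike-in scaling and 529 without both 4 h arrays, and 205 to 455 with 1 array left out. Genes lower (322) numbered 152 with the deposited scores and 201 to 386 with 1 array left out. The deposited scores cover 1734 of the 2697 genes. Lists that differed in mean level (3) were 6 with quantile normalization, 0 with an estimated correlation and 1 to 7 with 1 array left out. Lists that differed in the 12 h to 24 h change (3) were 1 with normexp, 5 with the median of probes, 8 with slide as a block, 5 with a trend in the spread, 5 with 24 h in wild type and 22 h in the null, 0 with an estimated correlation, and 0 to 5 with 1 array left out. The most genes 2-fold apart at 1 time (338) were 215 with normexp. Dusk-phase genes with a higher mean (90.9%) were 77.8% to 100% and dawn-phase genes with a lower mean (77.3%) 60.8% to 100% with 1 array left out, and the former 69.2% with a 26 h period, and without wild type at 12 h only 3 rhythmic genes were left. The swing of the allophycocyanin-like gene 637799218 was 0.24 with normexp and 1.27 as reported, and its peak moved. Normexp also lowered the swings of dim dawn-phase genes named in the report. Apart from the fewer genes or arrays of some settings, the cause was not tested.

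The ratio of null to wild-type swings (0.374) stayed between 0.156 and 0.436 in every alternative that gave a value. A peak time difference had no value under the reported settings and was 1.95 h with the deposited scores, 2.05 h with spike-in scaling, -2.65 h without wild type at 4 h and -1.7 h without both 4 h arrays. Of 3498 mean-level values for named genes and lists under the alternatives 3314 stayed on their side of the threshold. Another 139 lost and 45 gained the call, and 0 of those called as reported changed direction. Where the reported value was not called, a change of direction was not counted. Of 2940 wild-type swings 2178 stayed on their side, 575 lost and 186 gained the call. In 1 called swing the peak time moved far enough to count as reversed. Signal over background limits the genes named as not above background, where 3 of 4 cikA probes in the null give only a bound.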

Other observations

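The tests of slide, of single probes and neighbouring genes, and of lists with arrays swapped within a time, were chosen only after the result was seen. Several genes not yet named also changed in mean level, chosen here after their values were seen as members of the lists that kept their call under each alternative. A high light-inducible protein gene (637800442), of a family that protects photosystems in strong light, fell by 0.93 ± 0.16 on the log2 scale (adjusted p = 0.00491, 6 of 6 times). In nitrogen assimilation an Amt1-like ammonium transporter (637799384) fell by 0.61 ± 0.10. The FtsH proteases 637799360 and 637799417, which degrade membrane proteins, fell by 0.52 ± 0.09 and fell by 0.47 ± 0.09. Higher were the RNA polymerase alpha subunit (637800655, 0.54 ± 0.09), prepilin peptidase (637800377, 0.68 ± 0.09) and histidyl-tRNA synthetase (637800710, 0.67 ± 0.12).

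In the tiled region around the kai genes the probes give both strands, without a test. On the sense strand the null differed by 1.03 in kaiB, 0.08 in kaiA, -0.15 in the circadian phase modifier cpmA and -0.39 in a DevC gene (637799652). On the antisense strand the differences were 0.97, -0.00297, -0.09 and -0.31. Over 12 tiled genes the antisense level had a median Pearson correlation of 0.75 with the gene's own probes (0.981 in kaiB, -0.177 in the CheY-like gene 637799650). Carry-over of the sense signal was not tested. In a CheY-like gene (637799650) the antisense level was 0.53 higher in the null at 6 of 6 times, while the sense level differed by -0.03. In an acyl-CoA dehydrogenase-like gene (637799644) these were 0.50, at 6 of 6 times, and -0.13.

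In the deposited scores, in which each gene is scaled by its wild-type range, the column medians in wild type from 4 to 24 h were -0.03, -0.51, -0.22, 0.11, 0.38 and 0.20. In the null they were -0.00171, -0.15, -0.07, -0.13, 0.19 and 0.08.

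For the 651 genes that differed in mean level, 1 of 100 splits of the 12 arrays, the real split itself, gave as many, and the highest of the others gave 417. With arrays swapped only within a time, 1 of 32 splits gave as many, again the real split, and the highest of the others gave 150. A chance division of these arrays is therefore argued against. With 1 null strain and 1 array per genotype and time, the splits cannot exclude a chance difference between cultures. For the lists that differed in mean level chance could not be excluded, since 78 of 100 splits gave at least the real 3 and the highest of the others gave 12. These splits mix times, but with arrays swapped only within a time 20 of 32 gave at least 3, and the highest of the others gave 10. For the rhythm difference the real count was 0, which all 100 splits reach by construction, so the splits test nothing there, and the highest of the others gave 313. For the 253 genes rhythmic in wild type chance could not be excluded either: 7 of the 60 orderings of the 6 arrays gave as many, and the highest of the others gave 1083. Counts several times the real count, in the lists and the orderings, point to a structure of the samples or to genes that move together, which no test told apart. With an estimated correlation 0 lists passed.

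The dusk-phase genes had higher and the dawn-phase genes lower means in the null, with a gap of 0.98. A difference between the slides would leave no gap among the pairs of arrays on the same slide, and their gap was 0.64. The Fisher exact p of 1.22e-10 is over genes that are not independent. By pair the gap was 0.80 at 4 h, -0.17 at 8 h and 1.19 at 24 h, and the wild-type arrays of these pairs also served to choose the classes. Signal that depends on array brightness would lose the gap under quantile normalization, which kept 0.979 of it. Chance could not be excluded: 3 of the 32 splits that swap arrays within a time, the real one included, gave as large a gap. The genes and their classes were chosen anew in each split. The other splits with as large a gap (1.17 and 1.16) swapped the arrays of 1 time only. They kept most of the real division of the arrays, so this is a weak test of chance. As a hypothesis that was not tested, a clock output held near its evening state may account for the gap, although the null arrays at 4 h and 24 h lay nearest to wild type at the same time, and another difference between the strains stays open with 1 null strain.

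The cupin-domain regulator 637800483 was at least 42.7-fold higher in the null. A single probe that binds another transcript is argued against by the 4 probes, whose differences were at least 4.78 to 6.28 (log2) with the wild-type signal, mostly not above background, set to no less than the lowest spot above it. Read-through from an inserted sequence beside the gene stays open: of the 4 nearest genes none rose nearly as much, but on one side 637800484 rose by 0.35 (adjusted p = 0.0209) and 637800485 differed by 0.44 (adjusted p = 0.0621), against -0.11 and -0.00631 on the other side. The increase may follow from the loss of cikA, or from another difference between the strains, and with 1 null strain these cannot be told apart.

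The 75th percentile of signal over the spike-in probes rose late in the wild-type cycle, from -0.79 at 8 h to 0.24 at 20 h, a range of 1.02, against 0.36 in the null. Variation without order in time is argued against, since 1 of 60 orderings of the arrays, the real order, fitted a 24 h curve as well (R² 0.949, highest of the others 0.934), while in the null 10 of 60 did (0.771 and 0.953). A slide difference alone would raise the null as well, where slide 2 minus slide 1 was -0.0545 ± 0.12 (SE), against 0.51 in wild type. The null arrays of each slide are of different times, and the SE is taken over them. A slide difference and a change with time could offset each other there, so a slide difference stays open. Unequal amounts of added spike-in stay open: the spike-in signal itself had a range of 0.608, and no other control of known amount was available. A daily change in the amount of labelled RNA per culture may account for the pattern, as a hypothesis that this range leaves open.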
